A study of Mus musculus with 4 samples.

How the data were processed

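DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which cuts genomic DNA with restriction enzymes at CpG-rich sites, converts unmethylated cytosines with bisulfite and sequences the fragment ends. There were 4 libraries, 1 for each combination of cell type and genotype. The cell types were haematopoietic stem and progenitor cells (HSPCs, Sca1+Lin- cells of bone marrow) and mature B cells (B220+ cells of peripheral blood). Genotypes were wild-type and Sca1-BCL6Δ, on a CBAxC57BL/6J background. Sca1-BCL6Δ mice were designed so that a Bcl6 cDNA under the Sca1 promoter is expressed in HSPCs and is removed by Cre recombinase once Cd79a is switched on. Neither expression nor removal could be measured from these libraries. Per the labels, each library held DNA pooled from 6 to 9 mice, so no condition had a replicate library.

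Per the labels' protocols, DNA was cut with MspI and TaqI, fragments of 40 to 350 bp were selected, converted, amplified for 18 PCR cycles and sequenced on a GAIIx, giving 43930708 to 60139994 reads per condition. Per the submitters' methods text, the authors aligned the reads with an in-house Zymo Research pipeline to the 36-bp ends of predicted fragments of 40 to 220 bp. That pipeline required perfect matches of 12 bp, allowed no gaps and kept a read when its next best alignment had 2 more mismatches. Between 3378764 and 10295957 uniquely mapped reads per condition were stated there. The version of that pipeline was not given in the sources used here, and the build was mm9, per the labels. No step that removed PCR duplicates was recorded in the labels or the methods text, so reads of 1 CpG need not be separate molecules.

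The deposited CpG tables gave, for each CpG, the methylated and total read counts as a pair of whole numbers, with a coverage of at least 1 read. They also gave a score, which per the file headers was the mean methylation and which equalled 1000 times the methylated share, rounded down, at 100.0% of the CpGs in every library. Deposited read tables held 1 line per read, with the percent of its CpGs that were methylated and the count of its CpGs. The summed CpG counts of the reads equalled the summed coverage of the CpG table in all 4 libraries. Methylated and total counts were the input of every test, and the read tables were used only to describe reads with several CpGs.

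Mean coverage per CpG was 7.48 reads in the wild-type HSPC library, 5.45 in the Sca1-BCL6Δ HSPC library, 10.98 in the wild-type B cell library and 6.48 in the Sca1-BCL6Δ B cell library. CpGs with at least 10 reads made up 26.9%, 14.4%, 46.8% and 21.0% of the covered CpGs, in the same order. A simulation at the real CpGs and coverages, with the highest coverages capped, gave the precision. Reads were shared along chains of CpGs with gaps up to 50 bp. Such chains can be longer than the aligned 36-bp ends, so the sharing can be overstated. Tiles were changed by 50 percentage points, less where a CpG met the limit of its range. Of their CpGs that changed by at least 20 percentage points, the CpG test found 6.7% at the coverages of wild-type development. It found 4.5% at those of Sca1-BCL6Δ development, 8.9% at those of the HSPC genotype and 18.0% at those of the B cell genotype comparison. Of tiles changed by 50 percentage points, 52.5%, 44.0%, 44.0% and 57.0% were found in that order, with 3, 1, 1 and 0 unchanged tiles called. At 30 percentage points 8.5%, 4.5%, 5.5% and 12.0% of changed tiles were found.

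Before the data were examined, the samples were grouped from the labels and 4 comparisons of 2 libraries were fixed: Sca1-BCL6Δ against wild-type in HSPCs and in B cells, and B cells against HSPCs in wild-type and in Sca1-BCL6Δ mice. CpGs with at least 10 reads in both libraries were tested with Fisher's exact test, two-sided. Benjamini-Hochberg adjustment ran over all CpGs tested, and a CpG was called at an adjusted p under 0.05 and a difference of at least 20 percentage points. Fixed, non-overlapping tiles of 1 kb with at least 3 such CpGs were tested with a Cochran-Mantel-Haenszel test with continuity correction. For that test CpGs were thinned so that tested CpGs lay more than 50 bp apart, because neighbours share reads. Tiles were called at an adjusted p under 0.05 and a mean CpG difference of at least 20 percentage points. The p printed for a named tile is that of the exact conditional test on the same CpGs, chosen after the data were seen, which also called every named tile. The difference between the 2 genotype differences was tested per tile as the z of the difference of Mantel-Haenszel log odds ratios, with 0.5 added to each cell. These tests compared the reads of libraries, not conditions, and their p-values carry no variation between animals.

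Up to 5 called tiles per direction and comparison, those with the largest mean difference, were named. The tile rule stood in for a rule on promoters, because the gene table used here was on another assembly than mm9 and held no sequence. CpGs were therefore not tied to genes, and promoters, gene bodies and gene lists fixed beforehand were not analysed here. Positions are mm9 and 1-based.

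Global levels were means over autosomal CpGs with at least 10 reads in all 4 libraries, with standard errors from leaving out each of the 19 autosomes in turn. Pairs of libraries were compared after each CpG was thinned to the lowest of its 4 coverages. Sex chromosome coverage was summed with at most 50 reads per CpG. Intervals are 95% Wilson intervals, and a level of 0 is given with the limit that 3 counts allow. Intervals, floors and standard errors cover counting error or spread over CpGs and chromosomes only. The SE of a tile is the spread over its CpGs, and where these share reads it leaves out counting error of the shared reads.

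Alternatives were coverage minimums of 5 and 20 reads, a difference of 30 percentage points, thinning to equal coverage, leaving out CpGs above the 99.9th percentile of coverage, autosomes alone, tests on all CpGs of a tile, at least 5 CpGs per tile, and read-weighted levels. Chosen after seeing the data were an exact conditional test, Fisher's exact test on pooled counts of every CpG of a tile, a common coverage for the 4 libraries, replacement of the wild-type HSPC library, and a correction for its lower methylation. For the correction, methylated reads of the other library were set to unmethylated at a loss rate of 13.4% (HSPC genotype) or 14.9% (wild-type development). Each rate was measured at CpGs of at least 95% methylation in the 2 libraries outside the comparison. The correction was applied to every CpG, also where wild-type HSPCs were higher, as at CpGs of 10 to 20% in B cells (16.5% against 12.6% in Sca1-BCL6Δ HSPCs). There it widens the difference and can add lower calls. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and the tests were run on simulated data first.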

Results

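RRBS was performed on HSPCs and mature B cells of wild-type and Sca1-BCL6Δ mice, with 1 pooled library per condition and 4 libraries in all. The files held 4939456 reads with a CpG from wild-type HSPCs, 2614482 from Sca1-BCL6Δ HSPCs, 8336720 from wild-type B cells and 3612662 from Sca1-BCL6Δ B cells. These covered 1230862, 1012002, 1414224 and 1114078 CpGs, with median coverages of 6, 4, 9 and 5 reads. In all 4 libraries together 885724 CpGs were covered, and 70370 had at least 10 reads in each. Because no condition had a replicate library, no difference below could be set against variation between animals, and each test compared the reads of 2 libraries.

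Mean methylation was alike in the 4 libraries over the 70155 autosomal CpGs with at least 10 reads in each. Over the other sets of CpGs given in the part on processing the means lay further apart. The distribution over the 70155 CpGs was not alike. The mean was 23.84% (SE 0.24 over 19 autosomes) in wild-type HSPCs, 24.8% (SE 0.33) in Sca1-BCL6Δ HSPCs, 25.4% (SE 0.32) in wild-type B cells and 25.01% (SE 0.34) in Sca1-BCL6Δ B cells. In wild-type HSPCs 26.8% of these CpGs (SE 0.30) lay between 20 and 80% methylation and 9.5% (SE 0.18) above 80%. Sca1-BCL6Δ HSPCs, wild-type B cells and Sca1-BCL6Δ B cells had 14.9%, 14.1% and 12.8% in the middle range and 16.2%, 17.3% and 17.1% above 80%. At equal coverage the wild-type HSPC library differed from the other libraries by a mean of 10.5 to 10.8 percentage points per CpG (SE 0.06 to 0.07), whereas the other libraries differed from one another by 7.61 to 8.06 (SE 0.05). Pearson's r across CpGs, which are not independent replicates, was 0.893 to 0.898 for pairs with the wild-type HSPC library and 0.937 to 0.945 for the other pairs. Kendall's tau did not separate them, with 0.541 to 0.578 for pairs with the wild-type HSPC library and 0.547 to 0.573 for the others.

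**Figure D1:**
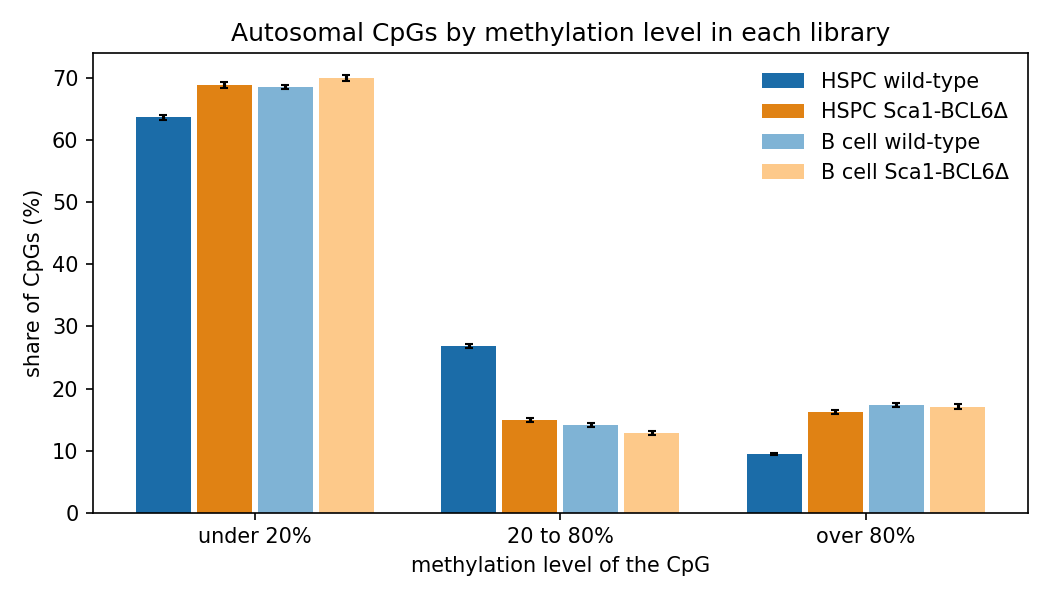
Share of 70155 autosomal CpGs (y axis, percent) with a methylation level under 20%, from 20 to 80% and over 80% (x axis) in each of the 4 libraries. Bars give the share and error bars the SE over 19 autosomes; the wild-type HSPC library has 26.8% of CpGs in the middle range, against 12.8 to 14.9% in the other libraries.

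The lower methylation of wild-type HSPCs lay at CpGs that were methylated elsewhere. Among 38883 autosomal CpGs with at least 98% methylation in the 2 B cell libraries combined, the mean level was 83.9% (SE 0.16) in wild-type and 95.8% (SE 0.05) in Sca1-BCL6Δ HSPCs. Among 9906 CpGs of 60 to 80% in B cells the levels were 57.7% (SE 0.26) and 69.5% (SE 0.20). The order was opposite at 42590 CpGs of 10 to 20% in B cells, with 16.5% (SE 0.06) in wild-type and 12.6% (SE 0.09) in Sca1-BCL6Δ HSPCs. Where classes were set by the 2 Sca1-BCL6Δ libraries instead, CpGs of at least 98% had 84.1% (SE 0.19) in wild-type HSPCs and 97.4% (SE 0.04) in wild-type B cells. The following HSPC and wild-type comparisons all contain this library.

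**Figure D2:**
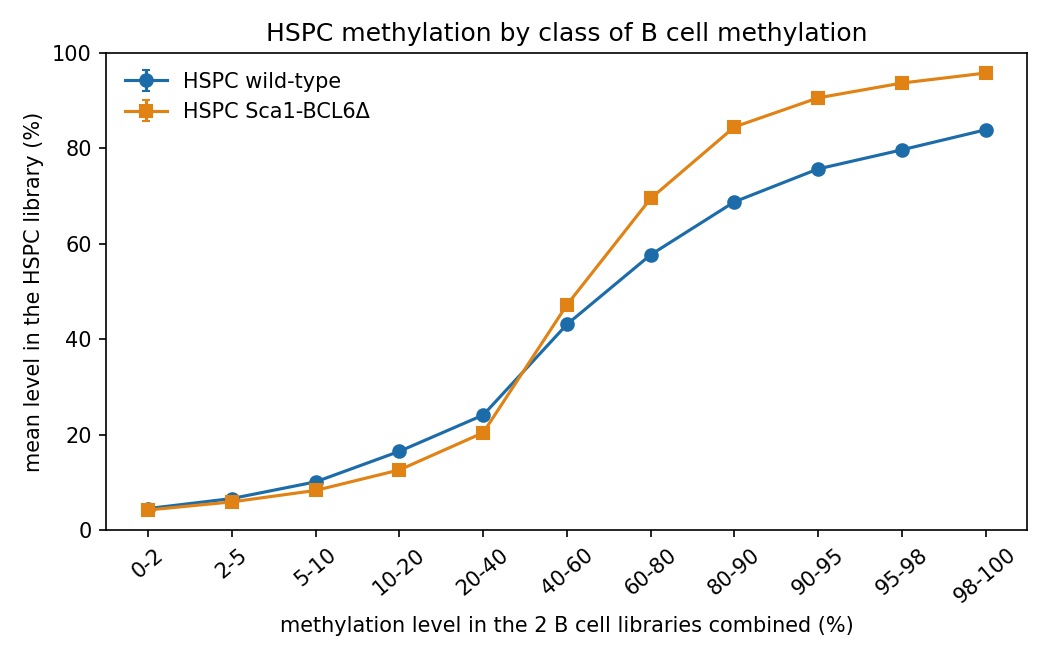
Mean methylation level of the wild-type and Sca1-BCL6Δ HSPC libraries (y axis, percent) at autosomal CpGs grouped by their level in the 2 B cell libraries combined (x axis, percent). Points are means over CpGs and error bars, mostly smaller than the points, the SE over autosomes; the curves separate in the upper classes, to 83.9% against 95.8% in the highest.

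The HSPC genotype comparison asked how methylation differed in the cells in which the Bcl6 transgene was designed to be expressed. Of 99971 CpGs tested, 25 were higher and 12 lower in Sca1-BCL6Δ than in wild-type HSPCs. The 25 higher CpGs had a median level of 97.9% in Sca1-BCL6Δ and 25.8% in wild-type HSPCs, and both B cell libraries had a median of 88.2% there. At the 12 lower CpGs the medians were 5.8% and 91.7%, with 90.8% in wild-type and 90.9% in Sca1-BCL6Δ B cells. By these medians B cells were nearer to Sca1-BCL6Δ HSPCs at the higher and to wild-type HSPCs at the lower CpGs, with exceptions. The higher CpG at chromosome 9, 86617440, had 4.8 and 13.9% in wild-type and Sca1-BCL6Δ B cells, and the lower one at chromosome 4, 141033759, had 22.2 and 5.9%.

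Among 11191 tiles, 1 was higher and 2 were lower in Sca1-BCL6Δ HSPCs. The tile at chromosome 14, 7892001 to 7893000, had 80.2% methylation against 39.1% in wild-type HSPCs, a difference of 41.1 percentage points (adjusted p = 9.2e-08, exact conditional test). The SE was 4.4 over 3 neighbouring CpGs, which share reads, with 72 to 79 reads each in Sca1-BCL6Δ and 419 to 451 in wild-type HSPCs. The lower tile at chromosome 1, 167246001 to 167247000, had 3.6% against 88.9% (adjusted p = 8.2e-10, exact test). The SE of the difference was 3.0 over 3 neighbouring CpGs, with 203 to 209 reads each in Sca1-BCL6Δ and 12 in wild-type HSPCs. The Sca1-BCL6Δ HSPC library was far deeper there than the others. On the X chromosome, the tile from 109008001 to 109009000 had 0.0% against 50.2% in wild-type HSPCs (SE 4.1 over 7 CpGs, adjusted p = 0.0021, exact test). The 0.0% rests on a count of 72 summed over 7 CpGs, of which 2 remained after thinning. Separate reads of that number would allow up to 4.2%, and shared reads allow more at this tile. Over the wider set of its CpGs with at least 5 reads, the level was 10.7% in Sca1-BCL6Δ and 47.8% in wild-type HSPCs (27 CpGs each) and 44.9% and 44.7% in wild-type and Sca1-BCL6Δ B cells (39 and 27 CpGs). X coverage in the Sca1-BCL6Δ HSPC library was 1.21% of autosomal coverage against 2.35 to 2.45% in the other libraries. Without the CpGs of highest coverage, 3 CpG calls were made among 98590. Of the 37 reported, 1 had at least 100 reads in both libraries, but a CpG was left out when either library was above its percentile. Calls deep in 1 library included those of the chromosome 14 tile (419 to 451 reads in wild-type HSPCs). The calls of the chromosome 1 tile were deep in Sca1-BCL6Δ HSPCs (203 to 209 reads). Leaving out CpGs also changes the Benjamini-Hochberg adjustment of those kept, so lost calls need not lie at the CpGs left out. With the loss rate of the wild-type library applied, 22 CpGs were called (7 higher, 15 lower). The chromosome 14 tile lost its call under that correction, with a difference of 28.6 percentage points, and the chromosome 1 and X tiles lost theirs when coverage was thinned, with differences of -86.1 and -47.1.

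The B cell genotype comparison asked what difference was present in mature B cells, in which the transgene was designed to have been removed. Its removal in these pools was not measured here. Of 198239 CpGs tested, 20 were higher and 14 lower in Sca1-BCL6Δ than in wild-type B cells. The higher calls included 8 in a deep stretch of chromosome 17 and 3 in a deep stretch of chromosome 13, with 14.3 to 47.0% and 21.0 to 23.9% in wild-type and 35.2 to 69.5% and 41.8 to 47.2% in Sca1-BCL6Δ B cells. Neighbouring CpGs of these deep stretches share reads, and whether those reads come from unique positions was not tested. The lower calls included 6 on chromosome 11 between 94990049 and 103659169, with 68.4 to 93.8% in wild-type and 0.0% in Sca1-BCL6Δ B cells at 10 to 15 reads, which allows up to 20 to 30% per CpG. At these 6 CpGs wild-type HSPCs had 35.7 to 100% and Sca1-BCL6Δ HSPCs, with 5 to 10 reads, 16.7 to 57.1%, and at chromosome 11, 103659169, the Sca1-BCL6Δ level was the higher one (40.0 against 35.7%). The remaining calls were spread over other positions, and the stretches were singled out after their values were seen.

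No tile among 19346 was called in B cells by the Cochran-Mantel-Haenszel test on read counts. An adjusted p below 0.05 was reached by 11 tiles, each with a mean difference under 20 percentage points, and an unadjusted p below 0.05 by 433 (2.2%). The exact conditional test called 0 tiles as well. The mean difference over CpGs was -0.38 percentage points. Without the CpGs of highest coverage, 4 CpG calls were made (2 higher, 2 lower). Of the 34 reported, 11 had at least 100 reads in both libraries. Others were deep in 1 library, as at chromosome 11, 120677495 (214 reads in Sca1-BCL6Δ and 67 in wild-type B cells). Here too lost calls need not lie at the CpGs left out. On simulated reads at this depth, 57.0% of tiles changed by 50 percentage points and 12% of those changed by 30 were called, so most tiles with smaller differences would be missed.

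The wild-type development comparison asked how methylation of B cells differed from that of HSPCs. Of 289105 CpGs tested, 1973 were higher and 148 lower in B cells. The higher CpGs had a median of 36.4% in HSPCs and 100% in B cells, and the lower ones 72.1% and 7.5%. Tiles showed the same direction, with 183 higher and 20 lower among 26489, on 20 and 12 chromosomes. The higher tiles had medians of 54.7% in HSPCs and 95.7% in B cells, and the lower ones 47.5% and 7.3%.

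Among named tiles higher in B cells, the largest differences were at chromosome 1, 152927001 to 152928000 (8.9% in wild-type HSPCs, 97.0% in wild-type B cells; SE of the difference 1.4 over 3 CpGs, adjusted p = 0.0049), and chromosome 3, 40973001 to 40974000 (24.2% and 98.6%; SE 5.5, adjusted p = 0.00059, exact conditional test). Tiles at chromosome 11, 94051001, chromosome 5, 114310001, and chromosome 15, 27623001, rose by 72.4, 70.6 and 65.4 percentage points (exact test, adjusted p = 0.0039, 0.0071 and 8.5e-05). Methylation was lower in B cells at chromosome 10, 120860001 to 120861000 (81.5% in HSPCs, 10% in B cells; SE 13.0, adjusted p = 0.0038) and chromosome 8, 26214001 to 26215000 (71.7% and 5.9%; SE 12.8, adjusted p = 8.3e-07, exact test). The other lower tiles, at chromosome 5, 24347001, chromosome 6, 37378001, and chromosome 10, 42581001, had 54.0%, 64.5% and 47.2% in HSPCs against 3.6%, 14.2% and 0.0% in B cells (exact test, adjusted p = 0.018, 0.016 and 0.011). At chromosome 10, 42581001, the 0.0% rests on a count of 40 summed over 3 CpGs, of which 1 remained after thinning. Neighbours share reads, so this allows more than the 7.5% of 40 separate reads. At chromosome 5, 24347001, the difference was -31.7 percentage points with a minimum of 5 reads and -27.3 with pooled counts, and the call was lost when at least 5 CpGs were required. Each named tile was tested on 1 or 2 CpGs because neighbours share reads, so the SE over CpGs does not measure the counting error of the difference. The tiles at chromosomes 15 and 8 kept their call at thinned coverage, while the other 8 lost it with differences about as large (66.7 to 87.9 higher, -70.4 to -47.2 lower). With the loss rate applied, the tiles at chromosome 8 and at chromosome 10, 120860001, kept their call, the higher tiles lost it with differences of 48.1 to 66.9, and the other lower tiles lost it with unchanged differences.

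The median level of Sca1-BCL6Δ HSPCs was close to that of B cells at the higher tiles. Over 98 of the 183 with at least 3 CpGs of 5 reads in every library, the medians were 58.1% in wild-type HSPCs, 90.7% in Sca1-BCL6Δ HSPCs, 94.8% in wild-type B cells and 94.6% in Sca1-BCL6Δ B cells. Over 14 of the 20 lower tiles they were 37.1%, 15.0%, 8.3% and 9.3%, and the tile on chromosome 8 was among the exceptions, with 72.2% in Sca1-BCL6Δ HSPCs and 5.6% in Sca1-BCL6Δ B cells. With the loss rate of the wild-type HSPC library applied to B cells, 103 CpGs (50 higher, 53 lower) and 17 tiles (6 higher, 11 lower) were called in place of 2121 and 203. With Sca1-BCL6Δ in place of wild-type HSPCs, 102 CpGs (68 higher, 34 lower) of 131588 and 4 tiles of 13991 were called.

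**Figure D3:**
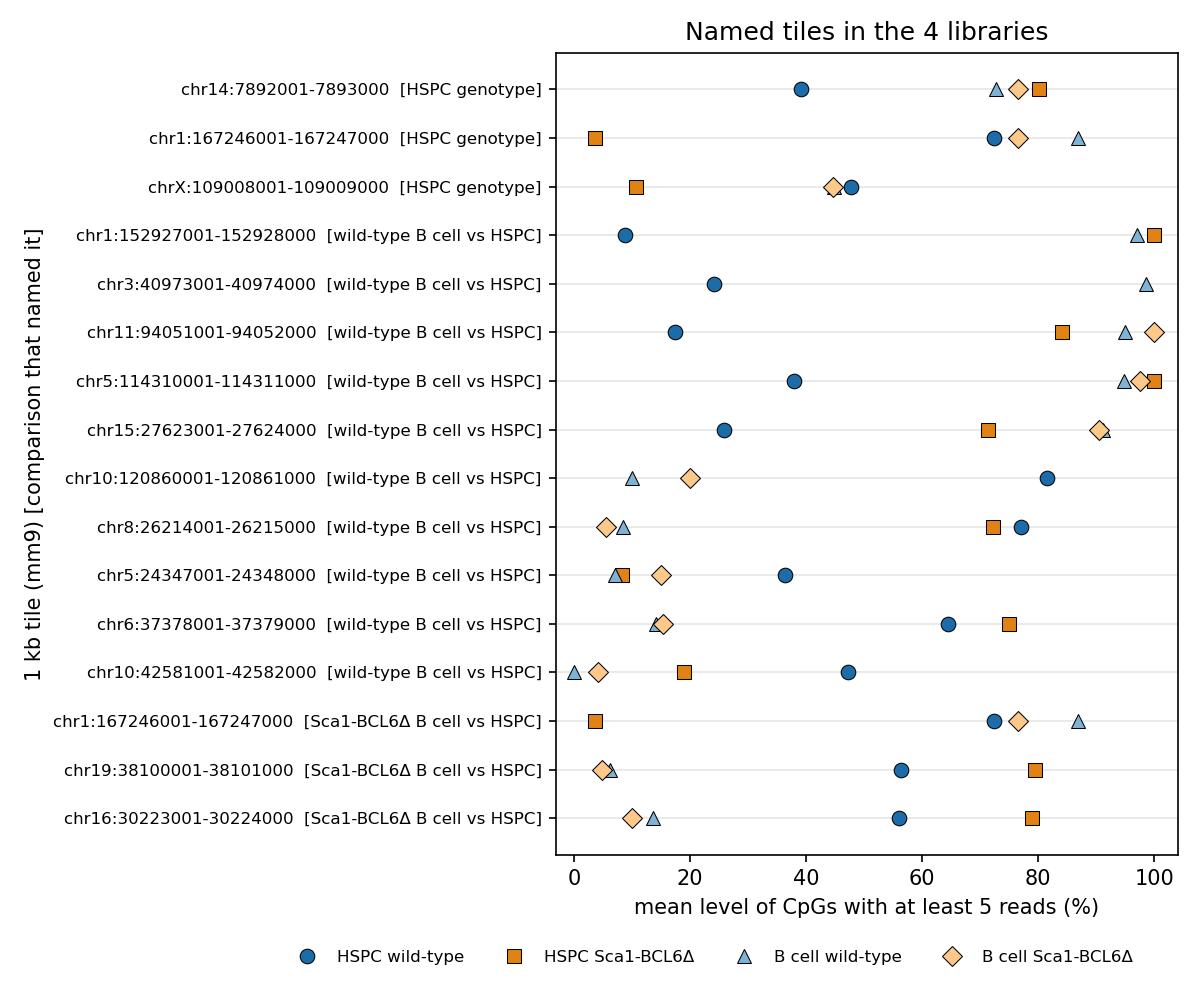
Mean methylation level (x axis, percent) of the CpGs with at least 5 reads in each named 1 kb tile (y axis, mm9 position and the comparison that named it), 1 symbol per library; a symbol is missing where a library had no such CpG. At the chromosome 8, 16 and 19 tiles both HSPC libraries lie at 56.0 to 79.5% and both B cell libraries at 4.8 to 13.7%.

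In Sca1-BCL6Δ mice few positions were called between B cells and HSPCs. Of 98408 CpGs tested, 9 were higher and 9 lower in B cells. Tiles at chromosome 19, 38100001 to 38101000, and chromosome 16, 30223001 to 30224000, were lower in B cells, with 4.8% against 79.5% (SE of the difference 5.1 over 3 CpGs; adjusted p = 0.0048) and 10.1% against 79.0% (SE 6.8 over 5 CpGs; adjusted p = 0.0089, exact conditional test). Wild-type cells had the same order at both, with 56.4% in HSPCs and 6.3% in B cells at the former, and 56.0% and 13.7% at the latter. The single higher tile was that of chromosome 1, 167246001, with 68.7% against 3.6% (exact test, adjusted p = 0.0017). Its 3 neighbouring CpGs had 203 to 209 reads each in HSPCs against 11 to 12 in B cells. Tested CpGs numbered 289105 in wild-type and 98408 in Sca1-BCL6Δ mice, and with the 4 libraries thinned to one coverage over 70370 CpGs the calls were 12 and 4. At the Sca1-BCL6Δ depths 44.0% of simulated tiles changed by 50 percentage points were called, and 4.5% of their CpGs that changed by at least 20. By the Cochran-Mantel-Haenszel test on read counts, 1.7% of the tiles tested had an unadjusted p below 0.05, against 11.1% in wild-type development. The 3 tiles lost their call when coverage was thinned, with differences of -71.8 (chromosome 19), -68.8 (chromosome 16) and 63.1 (chromosome 1) percentage points.

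Persistence of the genotype difference from HSPCs to B cells was tested at 70370 CpGs. Of 26 called in HSPCs and 16 in B cells, 1 was called in both, in the same direction, and 0 in opposite directions. Independent lists would share 0.0031 higher and 0.00045 lower CpGs. In simulated tiles changed by 50 percentage points, the CpG test found 8.9% (HSPC genotype) and 18.0% (B cell genotype) of CpGs that changed by at least 20. Most differences present in both cell types would therefore not be called in both, and the small overlap does not show that they were absent. The shared CpG, at chromosome 5, 129327798, had 93.8% methylation in Sca1-BCL6Δ HSPCs (15 of 16 reads, interval 71.7 to 98.9%) and 86.7% in Sca1-BCL6Δ B cells (13 of 15 reads, interval 62.1 to 96.3%). In wild-type HSPCs and B cells it had 0 of 13 and 0 of 32 methylated reads, which allows up to 23.1 and 9.4% (adjusted p = 0.00016 and 1.1e-06, Fisher's exact test). Across the 70370 CpGs the genotype differences of the 2 cell types had a Pearson r of 0.060 and a Spearman rho of 0.055 (Pearson r 0.197 over the 1851 CpGs with at least 20 reads), and across 9514 tiles an r of 0.031, with 0 tiles called in both. The 1851 CpGs included 181 of 1 deep stretch of chromosome 17, where neighbours share reads. There Sca1-BCL6Δ levels were the higher ones at 173 CpGs in HSPCs and at 177 in B cells. The r of 0.197 may rest on that stretch, and r without it was not computed. Counting error lowers such correlations, so the values of r and rho cannot show how much of the difference persisted.

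Whether the genotype difference itself changed between HSPCs and B cells was tested at 8487 tiles. No tile was called, while 5 had an adjusted p below 0.05 with a mean difference under 20 percentage points and 232 (2.7%) an unadjusted p below 0.05. This test found 1.0% of simulated tiles changed by 50 percentage points in Sca1-BCL6Δ HSPCs alone, so it had almost no power at this depth. A test on all CpGs called 107 tiles, and on simulated reads without any change it called 78 of the 8487 tiles.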

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

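All tests in this part were chosen after the results they bear on had been seen.

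Some regions could not enter the comparisons because reads came from 1 genotype alone: on the autosomes 69 tiles of 1 kb had at least 5 reads at some CpG in both Sca1-BCL6Δ libraries and none in either wild-type library. The same rule gave 8 and 6 tiles for the pairs that mix the genotypes, but 75 for the B cell pair and 3089 for the deeper wild-type pair, so the count alone does not exclude reads missed by chance. Their position argues against reads missed evenly over the genome as the whole cause. In the 5 densest windows of 5 Mb lay 39 of the 69, above the highest of 1000 random draws (15). The B cell pair had 9 in its densest windows (highest draw 14). The wild-type pair, with 141, also lay above its highest draw (135), though by less. The draws were not matched on depth in the absent libraries, so uneven depth could exceed them too. Stretches of chromosome whose strain of origin differs between the genotypes are a candidate explanation, with 23, 11 and 20 tiles on chromosomes 5, 12 and 19. Reads were aligned to mm9, so the sequence that departs from it in these tiles could be that of the wild-type mice. Both genotypes were on a CBAxC57BL/6J background, and the background of the transgenic and Cre lines was not tested. A sequence variant may therefore account for calls in such windows, among them the CpG called in both cell types at chromosome 5, 129327798 (window with 11 tiles) and the B cell call at chromosome 19, 24199638 (12 tiles).

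The Y chromosome carried reads in Sca1-BCL6Δ HSPCs, where 227 covered CpGs entered no comparison. Per 1000000 autosomal CpG observations there were 117.7 from Y in that library, against 15.7 in wild-type HSPCs, 5.8 in wild-type B cells and 6.1 in Sca1-BCL6Δ B cells, and X coverage was 1.21% of autosomal coverage against at least 2.35%. X chromosome CpGs under 20% methylation made up 44.9% of 3236 in this library and 13.9 to 17.6% in the others. These values are consistent with a larger share of male mice in the Sca1-BCL6Δ HSPC pool, and the Y reads argue against a change of X methylation with equal sex make-up. The labels give no sex, so a sex difference on autosomes stays open wherever this library was compared. That holds for the HSPC genotype comparison, Sca1-BCL6Δ development, persistence and the test between cell types. It also holds where this library replaced the wild-type HSPC library.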

How the results depend on the processing

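The exact conditional test, the pooled counts, the common coverage, the loss rate and the replacement of the wild-type HSPC library were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each comparison set 1 library against 1 library. Promoters, gene bodies and gene lists were not run, as no mm9 annotation was used here. Below, counts are calls, and those within 1.5 times of the reported count are left out.

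CpG calls with a minimum of 5 reads were 20 in the HSPC genotype comparison (37 reported). A minimum of 20 reads gave 903 in wild-type development (2121 reported) and 6 in Sca1-BCL6Δ development (18 reported). Thinning to the lower coverage gave 17, 262 and 3 in these comparisons. Leaving out the highest coverages gave 3 in the HSPC and 4 in the B cell genotype comparison (34 reported) and 7 in Sca1-BCL6Δ development. A common coverage gave 15, 16, 12 and 4 in the HSPC genotype, B cell genotype, wild-type and Sca1-BCL6Δ development comparisons. The loss rate gave 22 in the HSPC genotype comparison and 103 in wild-type development, and the replaced library 102.

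Tile calls reported were 3, 0, 203 and 3, in the same order. A minimum of 5 reads gave 7, 3, 1366 and 12, and of 20 reads 1, 1, 6 and 0. Testing all CpGs gave 359, 142, 2407 and 123, and pooled counts 3928, 611, 14864 and 1168. On simulated reads those tests called 102 to 245 and 139 to 319 unchanged tiles. The simulated pooled test held only CpGs with at least 10 reads in both libraries. That left 11191 tiles in the HSPC genotype comparison, against 46051 for the real pooled counts. Its calls are therefore no background for the real pooled counts. At least 5 CpGs gave 1, 31 and 1 without the B cell genotype comparison, thinning 1, 51 and 0, and read-weighted levels 1 in the B cell genotype comparison. The exact conditional test gave 11 in the HSPC genotype comparison and 425 in wild-type development. Pooled counts were mostly higher there (3057 higher, 871 lower; 13636 higher, 1228 lower), but mostly lower with the loss rate, which gave 1759 (471 higher, 1288 lower) and 3450 (1456 higher, 1994 lower), and the loss rate or the replaced library gave 17 or 4 in wild-type development.

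CpGs shared by the genotype comparisons numbered 0 with 20 reads (1 reported), and tiles 48 with pooled counts (0 reported). The test between cell types called 1 tile with 20 reads and 107 on all CpGs (0 reported).

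Mean levels followed the CpGs included. In wild-type HSPCs, Sca1-BCL6Δ HSPCs, wild-type B cells and Sca1-BCL6Δ B cells they were 36.6, 40.6, 41.3 and 41.0% with 5 reads, 19.7, 21.8, 20.6 and 22.3% with 20 reads, 40.4, 30.7, 51.1 and 38.2% over each library's own CpGs, and 32.8, 27.4, 36.3 and 35.2% when weighted by reads.

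Fewer reads or tested CpGs lower the power of the thinned, stricter and common-coverage settings by construction, and the cause of the other shifts was not tested. Named tiles were tested 141 times under the alternatives, and the call was kept 117 times, lost 24 times and turned in direction 0 times; 13 were lost when thinned, with differences about as large (-86.1 against -85.3 percentage points at chromosome 1, 167246001), and 9 with the loss rate. The size of the difference could change where the call was kept, as at chromosome 5, 24347001 (-50.4 percentage points reported, -27.3 with pooled counts).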

Other observations

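All tests in this part were chosen after the results they bear on had been seen, and the threshold for choosing CpGs below was relaxed after a stricter one left too few.

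CpGs that differed between B cells and HSPCs in wild-type mice were chosen on one part of the reads and measured on the rest. At 498 CpGs higher in wild-type B cells, levels were 58.4% (SE 1.0) in wild-type HSPCs, 83.7% (SE 0.9) in Sca1-BCL6Δ HSPCs, 88.9% (SE 0.7) in wild-type B cells and 88.1% (SE 0.8) in Sca1-BCL6Δ B cells. At 97 CpGs lower in wild-type B cells the levels were 38.9% (SE 2.4), 25.1% (SE 2.7), 17.0% (SE 1.6) and 16.5% (SE 1.8). At the 12 CpGs chosen as lower in Sca1-BCL6Δ B cells, wild-type cells had the same order, with 48.0% (SE 9.4) in HSPCs and 25.2% (SE 7.0) in B cells.

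Genotype differences called in B cells had mostly the same sign in HSPCs, at 26 of 31 CpGs with enough reads, with a median of 16.6 percentage points against 68.4 in B cells. Those called in HSPCs had the same sign in B cells at 20 of 34, with a median of 3.2 against 73.8. At CpGs with under 100 reads in every library the counts were 14 of 17 (median 26.2) for calls in B cells and 12 of 24 (median 0.3) for calls in HSPCs. A deep stretch of chromosome 17, from 39979959 to 39985654, had means over 181 CpGs of 23.4% in wild-type and 33.5% in Sca1-BCL6Δ HSPCs, and 25.6% and 38.1% in B cells (SD over CpGs 10.6 to 12.2). In the deep stretch of chromosome 13, 5 CpGs had 24.0% and 37.4% in HSPCs and 25.5% and 46.2% in B cells. In wild-type B cells reads per CpG reached 4471 and 1817 in these stretches, against a median of 18 over all CpGs of the B cell genotype test. The stretches held 8 and 3 of the calls in B cells, and whether their reads come from unique positions was not tested. Neighbouring CpGs share reads, so the sign counts over all calls are not counts of separate agreements. Tiles called from pooled counts in both genotype comparisons numbered 26 higher and 22 lower, where independent lists would share 13.5 and 4.8, and 26 in opposite directions against 20.1. The HSPC list behind this overlap turned from 3057 higher and 871 lower to 471 and 1288 with the loss rate applied. On simulated reads the pooled test called 139 to 319 unchanged tiles. That simulation held only CpGs with at least 10 reads in both libraries, so it gives no background for this overlap.

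The wild-type HSPC library had fewer methylated calls than the other libraries at CpGs methylated in both B cell libraries, and 3 explanations were weighed. If single cytosines had been over-converted independently of their neighbours, 3.3% of reads with 2 CpGs would be fully unmethylated, but 9.6% were. Fully unmethylated DNA mixed into the library would leave the share of reads with 1 methylated CpG near the 5.3% of Sca1-BCL6Δ HSPCs, but it was 11.8%, so this is unlikely to be the whole cause. Lower methylation in the cells of the wild-type HSPC pool could lower every region, and 475 of 475 windows of 5 Mb were lower. The windows held only CpGs over 97% methylated in the B cell libraries combined. Their means were 82.8% in wild-type and 95.6% in Sca1-BCL6Δ HSPCs (SD over windows 2.3 and 1.1), so this count could hardly differ. None of the 3 explanations by itself raises methylation, yet wild-type HSPCs were higher at CpGs of 10 to 20% in B cells (16.5 against 12.6%). A fault of the library might also lower every window, and with 1 library the causes cannot be told apart. A second wild-type HSPC library, with an unmethylated and a methylated spike-in, would separate them.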
